A study of Mus musculus with 10 samples.

How the data were processed

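Spinal cord RNA of C57BL/6 mice was measured by RNA sequencing in 10 libraries, which the labels place in 4 groups by sex and age: 2 male and 2 female libraries at 4 weeks and 3 male and 3 female libraries at 8 weeks. Per the labels' protocols, cords were removed, RNA was extracted with Trizol, an acid phenol reagent, and libraries were made by standard Illumina methods. The values the authors deposited are raw read counts per gene, 1 file per library, each with 26301 Entrez Gene identifiers and no normalization. Per the submitters' processing notes, TopHat2 2.1.0, a spliced aligner, featureCounts, a read counter, and the mouse build mm9 were used. The counting options, the strand setting and the annotation version are not given in the sources used here, so genes that overlap another gene, lie antisense to one or have near-identical copies, such as globins, ribosomal proteins, histones and some class II genes, are uncertain. No coordinates are given, since the build of the gene table used here differs.

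Gene symbols were looked up by identifier in a RefSeq table of assembly GRCm38.p6, used for names only. Of the 26301 identifiers 24191 had a symbol and 2110 did not, and the latter held at most 0.956% of a library's counts and stayed in under their identifiers. In all libraries 5314 identifiers had 0 counts. Library totals were 8534183 and 11594610 counts for male 4-week libraries 1 and 2, 8453559 and 10134260 for female 4-week libraries 1 and 2, 9554692, 8978589 and 10563942 for male 8-week libraries 1 to 3, and 9700205, 9711090 and 9582959 for female 8-week libraries 1 to 3. At these depths 1 CPM is close to 10 counts, and genes near that level are imprecise. Pairs of replicates differed by more than sampling noise, with chi-square over degrees of freedom between 1.92 and 11.2, the highest for the male 4-week pair, so each library was counted as a sample.

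Differences were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, its filter for low counts (filterByExpr, minimum count 10, minimum total 15), which left 15540 genes, and the two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Age over both sexes and sex over both ages came from an additive model with 7 residual degrees of freedom. Age within a sex, sex within an age and the interaction came from a model of the 4 groups with 6, in which every library lends to the estimate of spread. A gene's SE is its absolute log2 fold change divided by the square root of its F value. Group levels in text with an SD are TMM-scaled CPM, except those of the most abundant gene of each list of another tissue, such as Acta1, which are CPM of total counts, as are values per library, summed levels and the values of the plots per library. Where a group held few counts, the ratio of CPM has an exact 95% interval from the binomial split of the counts, and a group at 0 is set to a floor of 3 counts over the group.

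Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists with at least 4 tested members, and again with a correlation estimated per list and with fry, which tests whether a list's genes move in 1 direction. There were 32 lists: sterol synthesis enzymes, mature oligodendrocyte and myelin, oligodendrocyte precursor, newly forming oligodendrocyte, cell division, fibroblast and collagen matrix, astrocyte, microglia, immature neuron and axon growth, motor neuron, inhibitory neuron, excitatory neuron and synapse, fast-firing axon channels, perineuronal net and proteoglycan, endothelial and pericyte, ependymal, antigen presentation, interferon response, immediate early, glucocorticoid response, circadian clock, Y-linked, X-linked, erythroid, neutrophil and marrow, skeletal muscle, cartilage and bone, Schwann cell, dorsal root ganglion neuron, ribosomal protein, replication histone, and hypoxia and glycolysis. Of their 445 genes 10 were matched by an older symbol and 2 had no match. For age over both sexes camera called 14 lists, 2 of them with an estimated correlation (sterol synthesis enzymes and newly forming oligodendrocyte), and fry called 14. The lists, the models, the naming rule and the alternatives were chosen before the data were examined. Chosen after were 5 more lists (adrenal cortex, adrenal medulla, lung epithelium, adipose, kidney and liver), which had no list test, and 3 alternatives: leaving out male 8-week libraries 2 and 3, leaving out both male 4-week libraries, and adding the skeletal muscle score, the mean centred log2 CPM of that list, as a covariate.

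Genes were named by a rule. For age over both sexes and sex over both ages these were the 8 largest and 8 smallest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 log2 CPM and the same sign in both strata, and for the other comparisons the 5 largest and 5 smallest. Added to these were the 2 members of each list with the lowest p, all members of the Y-linked and X-linked lists, and the most abundant gene of each list of another tissue. Genes named outside the rule were chosen after their values were seen. In the age comparison these were Ugt8a, Klk6, Anln, Bcas1 and Hapln1. Between the sexes they were Srd5a2, Hsd3b1 and Akr1cl over both ages, and Cyp11b1, Akr1b7, Star and Cyp11a1 at 4 weeks. The others were the 9 single genes outside the lists, and the single adrenal and lung genes given with counts or levels per library. The results of some genes of the rule are not reported here.

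The steps were tested on simulated data drawn from the real means and library sizes, with 200 of 15540 genes changed. For age over both sexes 73.1% of 1.5-fold, 79.1% of 2-fold and 97.0% of 4-fold changes were recovered, and 5.68% of the calls were false. For sex over both ages these were 70.1%, 82.1% and 98.5%, with 11.2% false. For age in males they were 46.3%, 70.1% and 93.9%, with 3.45% false, and for age in females 40.3%, 79.1% and 89.4%, with 9.74% false. For sex at 4 weeks they were 29.9%, 65.7% and 89.4%, with 6.11% false, for sex at 8 weeks 50.7%, 83.6% and 95.5%, with 5.56% false, and for the interaction 14.9%, 41.8% and 90.9%, with 7.55% false. Most of these false shares lie above the nominal 5%. Each gene was drawn independently, without differences between libraries that many genes share. The shares recovered and false therefore do not cover such differences in these data. In the simulated list test the seeded list was called and 0 of 31 unchanged lists were. Its genes were drawn independently of each other. It therefore cannot tell how often camera calls unchanged lists whose genes move together.

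The alternatives were size factors by median ratio (RLE) and by upper quartile, no filter for low counts, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, each library left out in turn, the replicate number as a factor, the mean of the within-group contrasts of the 4-group model, and a fit of only the 2 groups compared. GC content and transcript length came from the longest GENCODE M21 transcript of each gene. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.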

Results

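RNA from spinal cord of C57BL/6 mice, a common inbred laboratory strain, was sequenced at 4 and 8 weeks of age in both sexes. There were 2 male and 2 female libraries at 4 weeks, and 3 male and 3 female libraries at 8 weeks, 10 in all. The deposited values were read counts per gene, and a library held between 8453559 and 11594610 counts. Between 18407 and 18884 genes had at least 1 count in a library. The 10 most abundant genes took 8.10% to 10.5% of a library's counts. The labels number the replicates without stating that each came from a separate animal, so p-values measure only the spread between these samples, which may be technical. Levels are given in CPM, counts scaled to a common library total, and changes as log2 fold changes with their standard error (SE).

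Sex-linked genes matched the labels in all 10 libraries. Xist, the RNA that silences an X chromosome in females, lay between 471 and 765 CPM in female libraries and at 0.334 CPM or less in male libraries. Ddx3y, a helicase gene on the Y chromosome, lay between 99.8 and 117 CPM in male libraries and at 0.104 CPM or less in female libraries. The principal component that held 34.7% of the variance separated the ages. The 8-week libraries lay between 11.8 and 21.5 on it, and the 4-week libraries between −47.6 and −13.9. Male 4-week library 1 stood apart at −47.6, while the other 4-week libraries lay at −21.1 or above. That library also held the most skeletal muscle transcripts, with a summed 2063 CPM over the 12 muscle genes.

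At 8 weeks 17 of 19 sterol synthesis enzymes, 13 of 22 myelin genes and 9 of 12 genes of newly forming oligodendrocytes, the glia that make myelin, were lower in the spinal cord than at 4 weeks, and 1 of those 12 was higher. Camera called the 3 lists lower, and the call of the myelin list was lost at adjusted p = 0.124 with an estimated correlation. Mal (Entrez Gene 17153), a proteolipid of compact myelin, fell by 1.05 on the log2 scale (SE 0.05), from 2225 ± 144 CPM (SD, n = 4) to 1076 ± 71.5 CPM (SD, n = 6). Cyp51 (Entrez Gene 13121), the lanosterol demethylase of sterol synthesis, fell by 0.54 (SE 0.05), from 348 ± 39.4 to 239 ± 9.46 CPM. Il33 (Entrez Gene 77125), an interleukin held in cell nuclei, rose by 1.5 (SE 0.09), from 55.7 ± 8.01 to 156 ± 13.7 CPM. In lists of tissues outside the cord, 12 of 12 muscle, 6 of 11 cartilage and bone, 12 of 12 neutrophil and marrow, 6 of 9 erythroid and 8 of 8 fat cell genes fell, and so did 13 of 20 collagen matrix and 20 of 33 cell division genes. Camera called these lists lower except the fat list, which had no list test, and the calls were lost at adjusted p values between 0.103 and 0.205 with an estimated correlation. The series' design names the 2 ages, and this comparison takes both sexes together. Of 15540 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1028 at an adjusted p under 0.05, 250 higher and 778 lower at 8 weeks. More than 2-fold changes were called for 13 higher and 263 lower genes. The median log2 fold change of all tested genes was 0.01.

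The count of 1028 became 474 without male 8-week libraries 2 and 3, which held lung transcripts, and 393 without both male 4-week libraries, which held adrenal transcripts and without which the age difference comes from the female libraries alone. It became 41 when the skeletal muscle score was added as a covariate, and 31 of those 41 were among the 1028. That score had a Pearson correlation of −0.912 with age, and it raised the median SE 2.42-fold. The 250 higher genes became 146 without male 4-week library 1, 550 without male 4-week library 2, 155 without male 8-week library 2, 143 without female 8-week library 1 and 159 without female 8-week library 3.

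Some calls of the genes named here for age over both sexes ended under alternatives. When the muscle score was added, Il33, Serpind1, H2-Aa, Mal, Cldn11, Gpr17, 9630013A20Rik, Hsd3b1 and Cyp11b1 kept their call. The other genes called by edgeR in that comparison and followed under the alternatives did not. Without male 8-week libraries 2 and 3 the calls of Aldh1l1, Chodl, Ddit4, Eif2s3y, Emid1, Gria1, Kcnab1, Kcnj8, Neu4, Pmp2, Pvalb, Rsad2 and Snap25 ended, at edgeR adjusted p values between 0.0589 and 0.212. Without both male 4-week libraries, which leaves the age difference in females, those of Abcb1a, Chodl, Emid1, Fcrls, Gria1, H2-Aa, Hapln4, Il17rb, Kcnab1, Marcks, Mpo, Ncan, Neu4, Pmp2, Prtn3, Pvalb, Rsad2, Sftpb and Snap25 ended, at 0.0533 to 0.942. Limma-voom did not call Emid1, Pvalb, Rsad2, Sftpb and Ucp1, and DESeq2 did not call Emid1, Pmp2, Pvalb and Sftpb. The mean of the contrasts within each sex did not call Eif2s3y, Emid1, Hsd3b1, Pmp2, Pvalb and Sftpb, and Emid1 was also lost with other size factors and with a filter of at least 1 CPM in 4 libraries.

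Among the genes with the largest increases, Il33 had an edgeR adjusted p of 9.45e-07, and all 6 of the 8-week libraries lay above every 4-week library. The unannotated transcript genes 1700063D05Rik and A230001M10Rik rose by 1.67 (SE 0.20) and 1.08 (SE 0.13), again with 6 of 6 libraries above. Il17rb, a receptor subunit for interleukin 25, rose by 1.31 (SE 0.23), Chdh, the mitochondrial choline dehydrogenase, by 1.3 (SE 0.24), and Serpind1, a thrombin inhibitor, by 1.02 (SE 0.16), each in 6 of 6 libraries. H2-Aa, a class II antigen-presenting molecule, rose by 0.99 (SE 0.22, edgeR adjusted p = 0.0150), with 3 of 6 libraries above every 4-week library, and without female 4-week library 2 its adjusted p was 0.0518. Sftpb, a surfactant protein of lung, passed the test (edgeR adjusted p = 0.0365), but it stood at 62.7 CPM in male 8-week library 2, at 5.87 CPM in male 8-week library 3 and at 0.206 CPM or less in the other 8. The call for Sftpb ended without any of the 4-week or the female 8-week libraries, at adjusted p values between 0.0545 and 0.196.

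The genes with the largest decreases were muscle, bone, fat and adrenal genes. Myh1 and Myh2, myosins of fast muscle fibres, fell by 4.14 (SE 0.39) and 4.07 (SE 0.59), and Csrp3, a protein of striated muscle, fell by 3.86 (SE 0.56). Mmp13, a collagenase of growing bone, fell by 3.98 (SE 0.50). Ucp1, the uncoupling protein of brown fat, fell by 4.06 (SE 0.76), and Fabp4, a fatty acid carrier of fat cells, fell by 3.72 (SE 0.54), from 77.8 ± 45.1 CPM to 6.40 ± 5.77 CPM. Hsd3b1 and Cyp11b1, enzymes of steroid hormone synthesis, were also called lower. Their counts lay almost wholly in the 2 male 4-week libraries, where Hsd3b1 had 548 counts against 3 over the other 8 libraries.

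**Figure D1:**
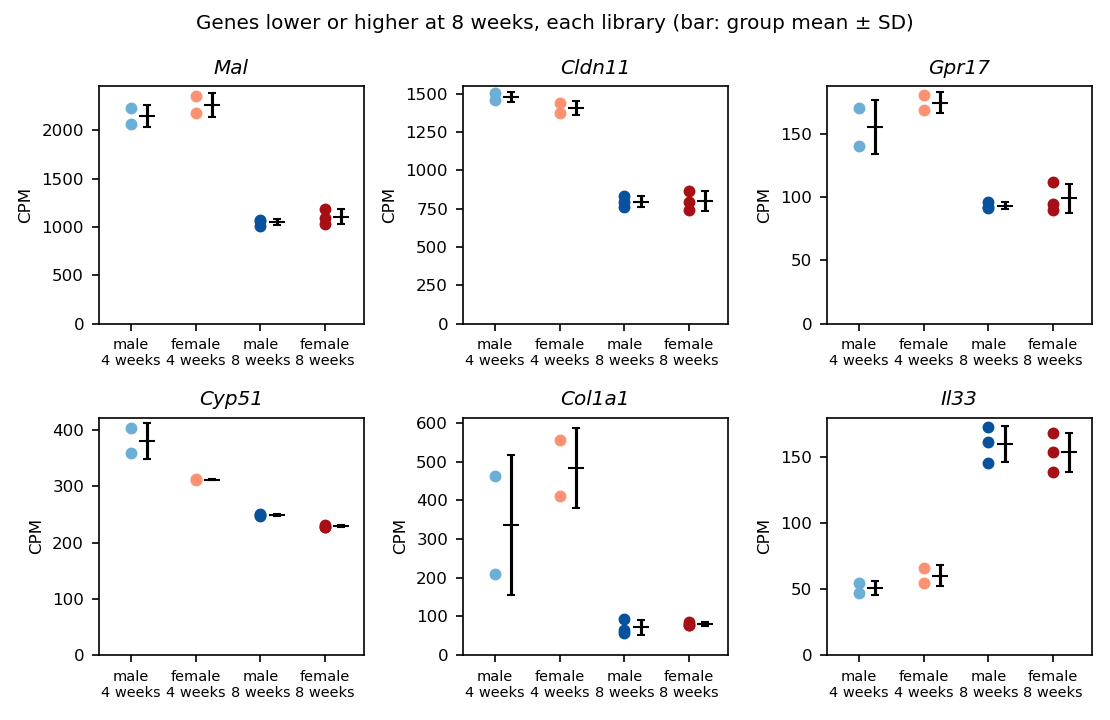
CPM of total counts of 6 genes in each library (points) of the 4 groups, with group means and SD as bars on linear axes from 0. Mal lay between 2072 and 2356 CPM in the 4-week libraries and between 1012 and 1188 CPM at 8 weeks, and Il33 lay between 46.8 and 65.6 CPM and between 139 and 173 CPM.

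Sterol synthesis enzymes, which make cholesterol, moved together. Of 19 tested, 17 fell and 2 did not pass, and adjusted over the list alone 19 fell. The median change was −0.41, and the list was called lower by camera (adjusted p = 1.26e-20) and kept its call at adjusted p = 0.0303 with an estimated correlation. For Cyp51 (edgeR adjusted p = 1.79e-05) all 6 of the 8-week libraries lay below every 4-week library. With the muscle score as a covariate, 0 of the 19 passed, the median was −0.32, the median SE rose from 0.07 to 0.16, and Cyp51 stood at −0.39 (SE 0.12, edgeR adjusted p = 0.145).

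Of 22 mature oligodendrocyte and myelin genes, 13 fell and 9 did not pass, and adjusted over the list alone 16 fell. Mal (edgeR adjusted p = 1.96e-07) and Cldn11, the tight junction protein of myelin, which fell by 0.87 (SE 0.06, edgeR adjusted p = 1.08e-06), lay lower in 6 of 6 libraries. Ugt8a, which makes the myelin lipid galactosylceramide, fell by 0.96 (SE 0.06). Klk6, a protease of mature oligodendrocytes, had a change of 0.01 (edgeR adjusted p = 0.962), and Anln, a septin-binding protein of myelin, one of 0.08 (edgeR adjusted p = 0.658). The median was −0.39, and camera called the list lower (adjusted p = 2.15e-15), a call lost at adjusted p = 0.124 with an estimated correlation. With the muscle score as a covariate, 3 of the 22 were lower and the median was −0.13 (median SE 0.14, from 0.06), while Mal stood at −0.98 (SE 0.14, edgeR adjusted p = 0.00551) and Cldn11 at −0.72 (SE 0.13, edgeR adjusted p = 0.0321). The Schwann cell list, which marks nerve roots, had a median of −0.21 and was not called (camera adjusted p = 0.161). Of its 9 genes, Gjc3, a connexin also made by oligodendrocytes, fell by 0.45 (SE 0.06), and Pmp2, a lipid carrier of peripheral myelin, by 1.14 (SE 0.29, edgeR adjusted p = 0.0300). Adjusted over the list alone, those 2 were lower. The call of Pmp2 ended without male 4-week library 1 (edgeR adjusted p = 0.106), female 4-week library 1 (0.0731), male 8-week library 3 (0.0521), female 8-week library 1 (0.0704) or female 8-week library 2 (0.0557).

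Among 12 genes of newly forming oligodendrocytes, 9 fell, 1 rose and 2 did not pass, and adjusted over the list alone 10 fell and 1 rose. Gpr17 (Entrez Gene 574402), a receptor of cells about to myelinate, fell by 0.79 (SE 0.07), from 166 ± 19.3 to 95.9 ± 8.12 CPM. The transcript 9630013A20Rik fell by 1.39 (SE 0.11), and Bcas1, a protein of early myelinating cells, rose by 0.21 (SE 0.05, edgeR adjusted p = 0.0162). The median was −0.63, and the list was called by camera (adjusted p = 4.65e-09) and at adjusted p = 0.0303 with an estimated correlation. Adding the muscle score as a covariate left 2 of the 12 lower at a median of −0.64. Of 12 oligodendrocyte precursor genes, Neu4, a sialidase, fell by 0.38 (SE 0.08), Emid1 fell by 0.54 (SE 0.15, edgeR adjusted p = 0.0482), and 10 did not pass, while 4 were lower adjusted over the list alone. That list's median was −0.22, and its camera call (adjusted p = 0.0101) was lost at adjusted p = 0.205 with an estimated correlation and at 0.120 without male 4-week library 2. The call of Emid1 ended without any library except male 4-week library 2 and male 8-week library 3, at adjusted p values up to 0.188.

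**Figure D2:**
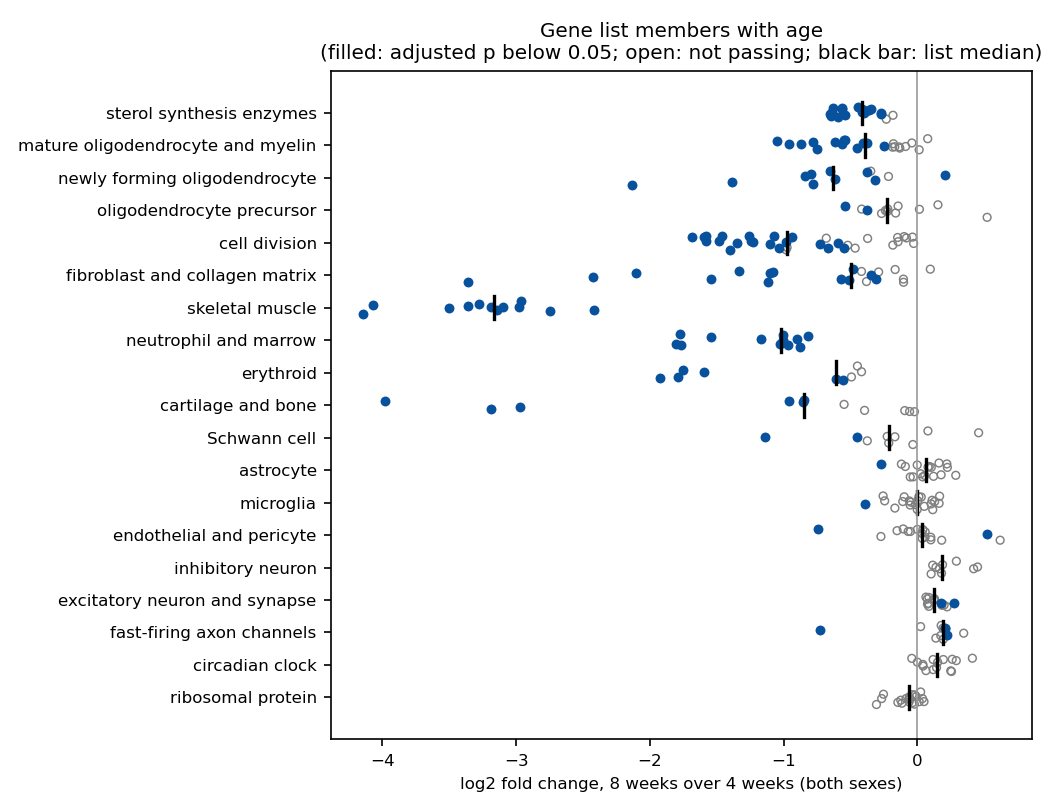
Log2 fold change of 8 over 4 weeks for the tested members of gene lists, each point a gene, filled where the adjusted p was under 0.05, with the list median as a black bar. The sterol synthesis enzymes lie at a median of −0.41 and the skeletal muscle genes at −3.16.

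Camera called 3 neuronal lists higher at 8 weeks, each by a small median. Of 13 excitatory neuron and synapse genes, Gria1, an AMPA receptor subunit, rose by 0.27 (SE 0.07, edgeR adjusted p = 0.0249) and Snap25, a protein of vesicle fusion, by 0.18 (SE 0.04, edgeR adjusted p = 0.0273), both with 6 of 6 libraries above every 4-week library. Adjusted over the list alone 3 rose, the median was 0.13, and camera's call (adjusted p = 0.00350) was lost at adjusted p = 0.205 with an estimated correlation. Of 9 inhibitory neuron genes none of the members passed over all genes or adjusted over the list alone, with Gad2, which makes the transmitter GABA, at 0.18 (SE 0.06, edgeR adjusted p = 0.106). Its list median was 0.18, and camera's call (adjusted p = 0.00206) was lost at adjusted p = 0.205 with an estimated correlation. Of 12 fast-firing axon channel genes, 2 rose, among them Kcnab1, a potassium channel subunit, by 0.22 (SE 0.05), and Pvalb, a calcium buffer of fast-firing neurons and of fast muscle, fell by 0.73 (SE 0.20, edgeR adjusted p = 0.0410). Adjusted over the list alone 7 rose and 1 fell, the median was 0.19, and camera's call (adjusted p = 0.00193) was lost at adjusted p = 0.205 with an estimated correlation. With the muscle score as a covariate the directions of all 3 lists reversed, at medians of −0.10 for excitatory (camera adjusted p = 0.898), −0.03 for inhibitory (0.366) and −0.14 for fast-firing genes (0.647), and Gria1 stood at −0.10 and Pvalb at 0.82, neither of which passed. Male 4-week library 1 had the lowest score of the 10 libraries in each list, −0.41, −0.49 and −0.24 in the same order, and the camera calls held without it. The ages overlapped in the excitatory list, where female 4-week library 2 scored 0.153. That lay above every male 8-week library (−0.154 to 0.132) and female 8-week library 3 (0.089). In the fast-firing list that female 4-week library scored 0.048, above male 8-week libraries 1 (−0.092) and 2 (0.04) and female 8-week library 2 (0.046). Male 4-week library 2 (−0.052) and female 4-week library 1 (−0.082) also lay above male 8-week library 1 there. In the inhibitory list the ages did not overlap. The call of Gria1 ended without male 4-week library 1 (edgeR adjusted p = 0.0735), female 4-week library 1 (0.0621), male 8-week libraries 1 (0.0549) and 3 (0.0577), or female 8-week libraries 1 (0.0521) and 3 (0.0640). That of Snap25 ended without female 4-week library 2 (0.0545), male 8-week library 2 (0.0604) or any of the female 8-week libraries (0.0513 to 0.0586), and that of Pvalb without any library except male 4-week library 2, female 4-week library 2 and female 8-week library 2 (0.0734 to 0.131).

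Other lists of cord cells were not called by camera. Of 14 immature neuron and axon growth genes 3 fell, among them Marcksl1, a regulator of actin in growing axons, by 0.80 (SE 0.07, edgeR adjusted p = 6.57e-06), and Marcks by 0.34 (SE 0.06), with a list median of −0.09. Of 12 motor neuron genes, Chodl, a membrane lectin, rose by 0.34 (SE 0.08) and Mmp9, a matrix protease of fast motor neurons and neutrophils, fell by 0.82 (SE 0.17, edgeR adjusted p = 0.0106), or 0.0565 without female 4-week library 2, with a list median of 0.13. Of 8 perineuronal net genes, Hapln4, a link protein, rose by 0.34 (SE 0.06), while the proteoglycan Ncan fell by 0.32 (SE 0.06) and Hapln1 fell by 0.38. Of 18 astrocyte genes only Aldh1l1, a folate enzyme, was called, and it fell by 0.27 (SE 0.07, edgeR adjusted p = 0.0236). That call ended without female 4-week libraries 1 (0.0721) or 2 (0.0788), male 8-week library 2 (0.0548), or female 8-week libraries 1 (0.0683) or 3 (0.0579). Of 21 microglial genes Fcrls fell by 0.39 (SE 0.08, edgeR adjusted p = 0.00971). Of 17 endothelial and pericyte genes, the drug transporter Abcb1a rose by 0.52 (SE 0.10) and the pericyte channel Kcnj8 fell by 0.74 (SE 0.20, edgeR adjusted p = 0.0417). The call of Kcnj8 ended without any library except male 4-week library 2, male 8-week library 3 and female 8-week library 3 (0.0637 to 0.115).

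Response lists showed few single changes. Of 13 antigen presentation genes H2-Aa rose, and adjusted over the list alone 3 rose, with Cd74, the class II chaperone, at 0.65 (SE 0.20, edgeR adjusted p = 0.0644). Of 13 interferon response genes Rsad2, an antiviral enzyme, fell by 0.91 (SE 0.23, edgeR adjusted p = 0.0316), a call that ended without any library except male 4-week library 2, female 4-week library 1 and female 8-week library 1 (0.0577 to 0.119). Of 12 glucocorticoid response genes Ddit4, a stress-induced inhibitor of growth signalling, fell by 0.35 (SE 0.09, edgeR adjusted p = 0.0333), a call that ended without either female 4-week library, male 8-week library 3 or any female 8-week library (0.0640 to 0.106). The replication histone list had 1 tested gene, the linker histone H1f2, which fell by 0.63 (SE 0.10), so it had no list test. None of the members passed in the ependymal (10 tested), immediate early (14), hypoxia and glycolysis (11), ribosomal protein (20), dorsal root ganglion neuron (7), X-linked (6) and circadian clock (15) lists. Of these, camera called the circadian clock list higher (adjusted p = 0.00548, median 0.14), a call lost at adjusted p = 0.446 with an estimated correlation and at 0.132 without male 4-week library 1. Of the 4 Y-linked genes Eif2s3y, a translation factor gene, fell by 0.58 (SE 0.12, edgeR adjusted p = 0.0156), or 0.108 without male 4-week library 1 and 0.0608 without male 8-week library 2. The female libraries held no counts of it, so the value rests on the male libraries.

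Skeletal muscle genes were all lower at 8 weeks, 12 of 12 over all genes and adjusted over the list alone, at a median of −3.16. Mylpf, a fast myosin light chain, fell by 3.50 (SE 0.37), and the most abundant, Acta1, was at 257 ± 166 CPM at 4 weeks and 27.8 ± 12.7 CPM at 8 weeks. The summed muscle level was 2063 CPM in male 4-week library 1, between 496 and 683 CPM in the other 4-week libraries, and between 40.8 and 155 CPM at 8 weeks. Of 11 cartilage and bone genes 6 fell, and 6 adjusted over the list alone, at a median of −0.85, with Bglap, the bone protein osteocalcin, down by a log2 change of −3.19 (SE 0.56). Col10a1, the collagen of growth cartilage, fell by 3.98 (SE 0.47). Alpl, the most abundant of these, was at 11.7 and 11.2 CPM at the 2 ages. In 8 fat cell genes, a list chosen after the data were examined, 8 fell at a median of −3.69. Their summed level overlapped between the ages, at 38.3 CPM in female 4-week library 2 and 50.4 CPM in female 8-week library 1. It lay between 175 and 289 CPM in the other 4-week libraries and between 7.95 and 23.0 CPM in the other 8-week libraries. Camera called muscle (adjusted p = 8.27e-16) and bone (2.07e-06), and both calls were lost, at adjusted p = 0.124 and 0.103 with an estimated correlation.

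Marrow and blood genes moved the same way. All 12 neutrophil and marrow genes fell, over all genes and adjusted over the list alone, at a median of −1.02. Mpo, the peroxidase of neutrophil granules, fell by 1.81 (SE 0.28), Prtn3, a granule protease, fell by 1.54 (SE 0.27), and the most abundant, S100a9, was at 117 and 56.0 CPM. Of 9 erythroid genes 6 fell, and 9 adjusted over the list alone, at a median of −0.61. Slc4a1, the red cell anion exchanger, fell by 1.79 (SE 0.25), and the globin Hba-a1 was at 291 and 196 CPM. Camera called marrow (adjusted p = 3.15e-09) and erythroid genes (5.1e-07), and both calls were lost, at adjusted p = 0.205 and 0.149 with an estimated correlation.

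Beside these, 20 of 33 cell division genes fell, and 24 adjusted over the list alone, at a median of −0.97. Top2a, which untangles replicated DNA, fell by 1.48 (SE 0.19, edgeR adjusted p = 3.18e-04), and Mki67 (Entrez Gene 17345), a marker of dividing cells, fell by 1.58 (SE 0.24), both with 6 of 6 libraries below every 4-week library. Of 20 fibroblast and collagen matrix genes 13 fell, and 13 adjusted over the list alone, at a median of −0.50. Postn, a matrix protein of growing connective tissue, fell by 3.36 (SE 0.25), and Col1a1 (Entrez Gene 12842), the main collagen of bone and skin, fell by 2.42 (SE 0.19), from 413 ± 148 to 75.9 ± 13.2 CPM. Camera called division (adjusted p = 1.87e-15) and collagen genes (4.16e-12), and both calls were lost, each at adjusted p = 0.124 with an estimated correlation. The summed neutrophil and marrow level, which fell alongside, was 653 CPM in male 4-week library 1, between 231 and 358 CPM in the other 4-week libraries and between 135 and 231 CPM at 8 weeks. In the fit with the muscle score, 0 of the 33 cell division genes passed, at a median of −0.30.

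**Figure D3:**
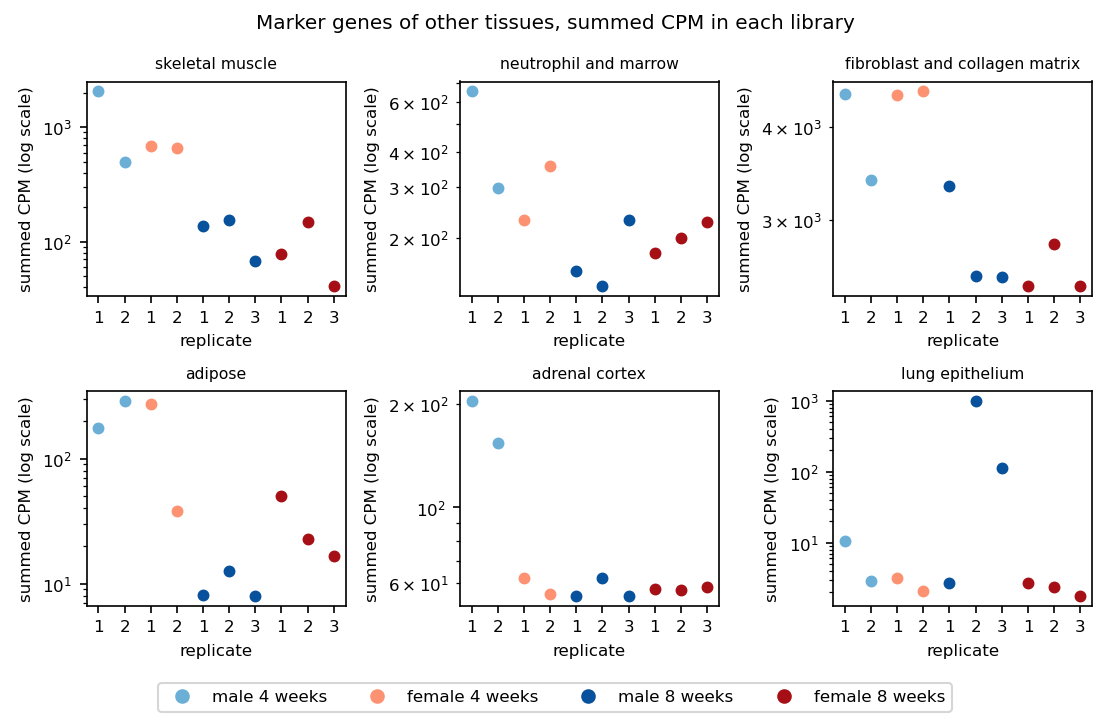
Summed CPM of marker lists of other tissues in each of the 10 libraries (points, by group and replicate), on log axes. Skeletal muscle reaches 2063 CPM in male 4-week library 1 and lung 985 CPM in male 8-week library 2. In the collagen list Sparc alone lies between 1734 and 2694 CPM, and its source was not tested.

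Transcripts of the adrenal gland appeared in both male 4-week libraries. Over 14 genes of the adrenal cortex, a list chosen after the data were examined, they held 204 and 154 summed CPM, against 55.1 to 62.3 CPM in the other 8 libraries. Cyp21a1, the adrenal steroid 21-hydroxylase, had 364 counts in the 2 male 4-week libraries and 1 in the other 8, a ratio of 1387 (95% interval 247 to 54918). Hsd3b1 had a ratio of 696 (237 to 3385). Pnmt, which makes adrenaline, had 56 counts against 0, at least 71.1-fold higher against a floor of 3 counts over the other 8 libraries. Dbh, which makes noradrenaline, had a ratio of 24.4 (9.43 to 80.2), while Th and Chga, also made by neurons, had ratios of 1.44 and 0.909. Of the 12 tested cortex genes 8 were lower at 8 weeks, as were 2 of 6 adrenal medulla genes. Lung epithelial genes, 12 in another such list, summed to 985 CPM in male 8-week library 2 and 114 CPM in male 8-week library 3, against 1.77 to 10.4 CPM in the other 8, and 1 of them was higher at 8 weeks. Scgb1a1, a secretory protein of airways, was at 272 and 32.2 CPM in those libraries, and Sftpc, another surfactant protein, at 385 and 43.0 CPM. Of the kidney and liver list 2 genes could be tested, and 0 passed. Ratio intervals and floors cover counting error only.

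Male and female cords were also compared between ages separately. In males Il33 rose by 1.66 (SE 0.12), 1700063D05Rik by 1.61 (SE 0.27) and Arl4d, a small GTPase, by 1.31 (SE 0.22). In females Chdh rose by 2.0 (SE 0.30), 1700063D05Rik by 1.74 (SE 0.30) and Il33 by 1.34 (SE 0.12). Ugt8a fell by 1.12 (SE 0.06) in males and by 0.79 (SE 0.06) in females, and Mal fell by 1.05 in both (SE 0.08 each). In males 12 of 19 sterol synthesis enzymes and 10 of 22 myelin genes fell, 18 and 16 adjusted over the list alone, and in females 9 and 11 fell, 18 and 13 adjusted over the list alone. The edgeR quasi-likelihood test called 501 genes in males (3 libraries against 2), 130 higher and 371 lower, and 226 in females (3 against 2), 37 higher and 189 lower. Of the male calls 25.9% were higher, against 47.5% of 1199 without male 4-week library 2 and 8.00% of 175 in a fit of only the groups compared. Such a fit called 398 in females, and 340 were called there without a filter for low counts.

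Camera called both of these lists in each sex. These calls were lost, at adjusted p = 0.103 for sterol synthesis and 0.161 for myelin in males, and 0.0804 and 0.285 in females, with an estimated correlation. Newly forming oligodendrocyte genes had 5 of 12 lower in each sex, 8 in males and 10 in females adjusted over the list alone (adjusted p = 0.103 and 0.0804 with an estimated correlation). Cell division genes had 9 of 33 lower in males and 1 in females, 21 and 9 adjusted over the list alone. Neutrophil and marrow genes had 8 of 12 lower in males and 0 in females, 12 and 1 adjusted over the list alone, and skeletal muscle genes 12 and 9. Over the 15540 genes, which are not independent replicates, the age changes of the sexes had a Pearson r of 0.574 and a Spearman rho of 0.417. Called lower in both sexes were 141 genes, where independent lists give 4.51, and called higher in both were 11, where they give 0.310. Of the 501 male calls 476 had the same sign in females, and of the 226 female calls 226 had the same sign in males.

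Genes named for the largest decreases were mostly of other tissues in both sexes. In males Cfd, a complement factor of fat cells, and Myh2 fell by 5.96 (SE 1.04) and 5.38 (SE 0.83), beside Hsd3b1, Cyp21a1 and Cyp11b1. In females Myh1 fell by 4.19 (SE 0.61), Postn by a log2 change of −3.37 (SE 0.38), Mylpf fell by 3.25 (SE 0.57), Mmp13 fell by 3.24 (SE 0.62) and Ckmt2, a muscle creatine kinase, fell by 3.44 (SE 0.75). Without male 8-week libraries 2 and 3 the male count was 15 and the female count 118. Without single libraries the male count was 247 (male 4-week library 1), 1199 (male 4-week library 2), 239, 188 and 258 (male 8-week libraries 1, 2 and 3) and 301 (female 8-week library 1). The female count was 392 and 394 (male 4-week libraries 1 and 2), 94 and 68 (female 4-week libraries 1 and 2) and 62, 141 and 66 (female 8-week libraries 1, 2 and 3). Without male 8-week libraries 2 and 3 the calls of 1700063D05Rik, Arl4d, Cfd and Myh2 ended in males (edgeR adjusted p from 0.117 to 0.286), and those of 1700063D05Rik, Ckmt2 and Mmp13 in females (0.0524 to 0.0975). Limma-voom did not call Cfd (0.131) and Myh2 (0.137) in males, or Ckmt2 (0.239), Mmp13 (0.113) and Myh1 (0.0689) in females, and Ckmt2 was lost with upper-quartile factors (0.0504). When the muscle score was added, 1700063D05Rik (0.112), Cfd (0.0534) and Myh2 (0.644) were not called in males, nor were 1700063D05Rik, Chdh, Ckmt2, Mmp13, Myh1, Mylpf and Postn in females (0.164 to 0.898). The call of Cfd ended without male 8-week library 1 (edgeR adjusted p = 0.0537) and that of Chdh without female 4-week library 2 (0.0902). In females 1700063D05Rik was not called without female 4-week library 1 (0.135), female 4-week library 2 (0.0835) or female 8-week library 1 (0.0771). Ckmt2 lost its call without any library but the 2 male 4-week ones (0.0607 to 0.240), Mmp13 without any female library (0.0612 to 0.169), and Mylpf without any female library but 8-week library 2 (0.0749 to 0.113).

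**Figure D4:**
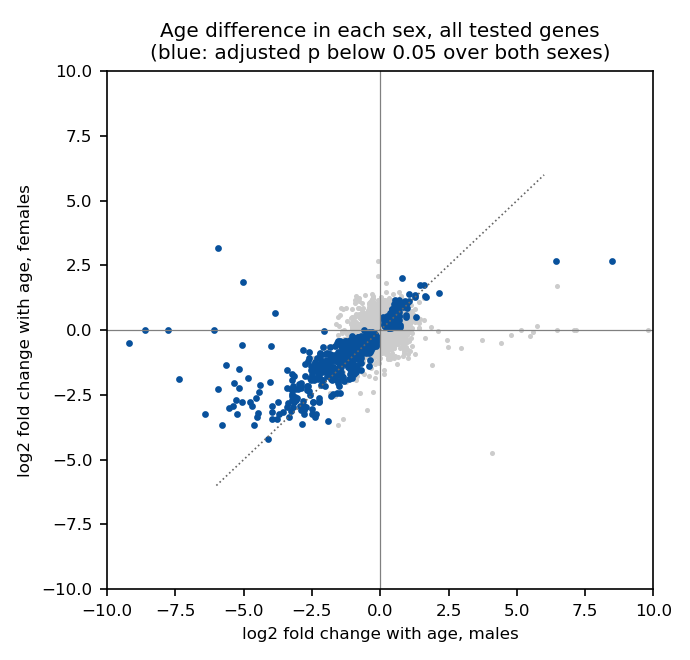
Log2 fold change of 8 over 4 weeks in females against that in males, each point a tested gene, blue where called over both sexes, with a dotted line of equal change. The 2 sets of changes have a Pearson r of 0.574 over 15540 genes.

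Whether the age change itself differed between the sexes was tested by an interaction. Star (Entrez Gene 20845), which carries cholesterol into mitochondria for steroid synthesis, and Cyp11a1 (Entrez Gene 13070), the enzyme that starts steroid synthesis, had higher female than male changes, by 2.01 (SE 0.17, edgeR adjusted p = 9.63e-04) and 4.49 (SE 0.53, edgeR adjusted p = 0.0144). Star stood at 41.2 and 35.8 CPM in the male 4-week libraries and between 7.72 and 9.80 CPM in the other 8. These were the 2 genes called by edgeR, 2 higher and 0 lower, and both belong to the adrenal cortex list. Of 15540 genes 749 had an unadjusted edgeR p under 0.05, no more than chance alone would give. The call of Cyp11a1 ended in limma-voom (adjusted p = 0.0943), and by edgeR without either female 4-week library, male 8-week library 1 or any female 8-week library, at adjusted p values between 0.0652 and 0.179, which left a count of 1, and without male 8-week libraries 2 and 3 together the count was 0.

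Between the sexes, over both ages, the genes that differed were sex-linked genes, adrenal genes and 3 others. Xist (Entrez Gene 213742) was higher in females by a ratio of 3045 (95% interval 1656 to 6351). Ddx3y (Entrez Gene 26900) was higher in males by a ratio of 2569 (711 to 21217), on 5315 counts against 2, and Uty, a Y-linked demethylase gene, by a ratio of 883 (158 to 34895). Eif2s3y and Kdm5d, also Y-linked, were at least 674-fold and at least 318-fold higher in males, against a floor of 3 counts over the 5 female libraries. The edgeR quasi-likelihood test called 14 genes, 4 higher and 10 lower in females (5 libraries of each sex), and 1143 genes had an unadjusted p under 0.05. The count of genes called was 60 without a filter for low counts and 38 with the replicate number as a factor. DESeq2 called 35 and shared 11 of the 14. The count was 24 with the muscle score and 9 as the mean of the contrasts within each age.

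Of the 6 X-linked genes Xist, Ddx3x and Kdm6a, which escape X inactivation in the mouse or act in it, were higher in females, and adjusted over the list alone 6 were. Ddx3x, the X-linked partner of Ddx3y, rose by 0.46 in females over males (SE 0.06, edgeR adjusted p = 0.00486), and Kdm6a, a histone demethylase, by 0.62 (SE 0.10, edgeR adjusted p = 0.0225), each with 5 of 5 female libraries above every male library. Kdm5c stood at 0.47 (edgeR adjusted p = 0.111), Eif2s3x at 0.47 (0.241) and 5530601H04Rik at 0.42 (0.621). The other 3 were Srd5a2, Gm2223 and Plekhf1. Srd5a2, a 5-alpha reductase that activates testosterone, was chosen after its values were seen, and had a change of −2.25 (SE 0.35, edgeR adjusted p = 0.0225), a call not followed under the alternatives. Gm2223, a predicted gene, was higher by 0.65 (SE 0.08, edgeR adjusted p = 0.00152), and Plekhf1, a lysosomal adaptor, with a change of −0.79 (SE 0.12, edgeR adjusted p = 0.0225), each in 5 of 5 libraries. The adrenal genes lower in females were Cyp21a1, Cyp11b1, Hsd3b1 and Akr1cl, which belong to the adrenal cortex list. Without both male 4-week libraries only 8-week libraries compare the sexes, and 9 genes were called. The call of Ddx3x ended without male 8-week libraries 2 and 3 (edgeR adjusted p = 0.112, over the alternatives 2.99e-09 to 0.112), as did those of Kdm6a and Plekhf1 (0.114 each). Cyp21a1 was not called by DESeq2 (0.916), by limma-voom (0.186) or as the mean of the contrasts within each age (0.523), nor were Kdm6a (0.0804) and Plekhf1 (0.0854) in the last of these. The count was 28 without male 4-week library 2 and 24 without male 8-week library 2. The call of Kdm6a ended without female 4-week library 2 (edgeR adjusted p = 0.119), male 8-week libraries 1 (0.0714) or 2 (0.0556), or any female 8-week library (0.0955 to 0.109). That of Plekhf1 ended without female 4-week library 2 (0.0790), male 8-week library 1 (0.0534) or any female 8-week library (0.0629 to 0.0955).

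**Figure D5:**
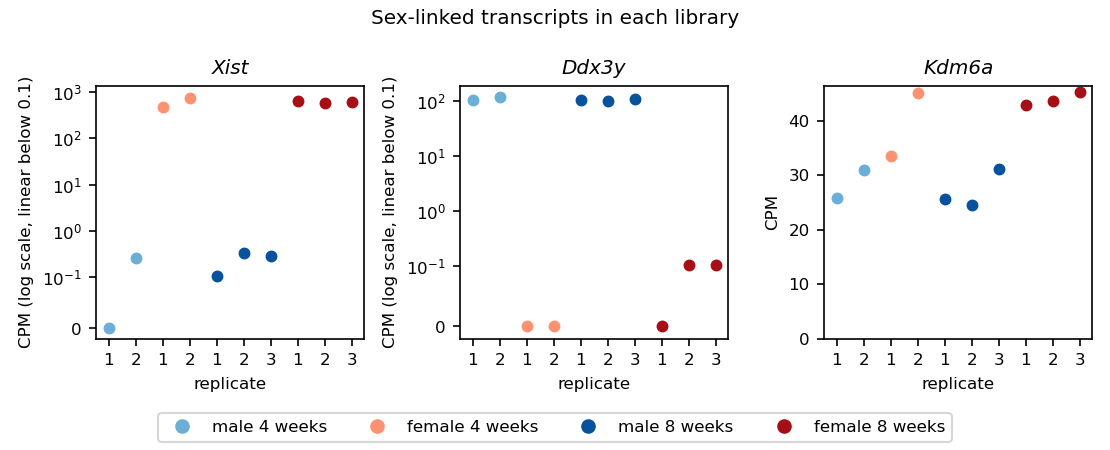
CPM of Xist and Ddx3y (log axes, linear below 0.1) and of Kdm6a (linear axis) in each of the 10 libraries, by group and replicate. Xist lies between 471 and 765 CPM in female libraries, and Ddx3y between 99.8 and 117 CPM in male libraries.

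Camera called 16 lists between the sexes, and 2 of these held with an estimated correlation. The Y-linked list, with 4 of 4 lower over all genes and adjusted over the list alone, had adjusted p = 7.8e-04 with an estimated correlation, and the X-linked list had adjusted p = 0.0211 with an estimated correlation. The dorsal root ganglion neuron list, which marks sensory ganglia, had a median of −1.18 and 5 of 7 genes lower adjusted over the list alone, with Avil at −2.19 (SE 0.40, edgeR adjusted p = 0.0756), but 0 passed over all genes. Its camera call (adjusted p = 8.92e-07) was lost at adjusted p = 0.320 with an estimated correlation. Its summed level lay between 53.1 and 86.4 CPM in male and between 41.7 and 59.0 CPM in female libraries. Glucocorticoid response genes had 4 of 12 lower adjusted over the list alone, among them Nfkbia at −0.56 (SE 0.10, edgeR adjusted p = 0.0593) and Sgk1 at −1.11 (SE 0.23, edgeR adjusted p = 0.155), and adjusted p = 0.689 with an estimated correlation. Its camera call also ended without male 8-week library 2 (adjusted p = 0.0713) or female 8-week library 3 (0.0669). The other 12 lists called had medians between −0.66 (skeletal muscle) and 0.14 (fast-firing axon channels) and 0 members passing over all genes. Their adjusted p values lay between 0.346 and 0.740 with an estimated correlation, and without male 8-week library 2 the number of lists called was 10.

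At 4 weeks alone (2 libraries of each sex) the sexes differed in Xist, the 4 Y-linked genes and 6 adrenal genes. The latter were Cyp11b1, Cyp21a1, Hsd3b1, Akr1b7, Star and Cyp11a1, all lower in females and all members of the adrenal cortex list. Together these were the 11 genes called by edgeR, 1 higher and 10 lower, and 1143 had an unadjusted p under 0.05. Klk6 had the lowest p of the myelin list, at −0.62 (SE 0.14, edgeR adjusted p = 0.345). Of the X-linked genes 5 of 6 were higher adjusted over the list alone. Without male 4-week library 2 the count was 116, of which 58.6% were higher in females. DESeq2 called 31 genes, 87.1% of them higher, and shared 1 of the 11. It gave no adjusted p for Ddx3y, Eif2s3y, Kdm5d, Cyp21a1 and Hsd3b1. The count was 17 without a filter for low counts, 7 with a filter of at least 1 CPM in 4 libraries and 18 with the muscle score.

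At 8 weeks alone (3 libraries of each sex) Penk (Entrez Gene 18619), the precursor of the enkephalin opioid peptides, was lower in females, with a change of −0.48 (SE 0.07, edgeR adjusted p = 0.0249), from 223 CPM in males to 160 CPM in females, and 3 of 3 female libraries lay below every male library. Ddx3x was higher by 0.54 (SE 0.07, edgeR adjusted p = 0.0127). Besides these, Xist and the 4 Y-linked genes made up the 7 genes called, 2 higher and 5 lower. Of 15540 genes 751 had an unadjusted edgeR p under 0.05, no more than chance alone would give. The count of genes called was 34 without a filter for low counts, 26 by DESeq2 and 23 with the replicate number as a factor. It was 19 in a fit of only the groups compared and 13 with the muscle score, and every one of these alternatives held all 7. The call of Penk ended without any of the 6 libraries compared, at adjusted p values between 0.0576 and 0.295. That of Ddx3x ended without any of them except male 8-week library 3 (0.0773 to 0.122). Without male 8-week libraries 2 and 3 together the values were 0.351 for Penk and 0.554 for Ddx3x. Of 12 glucocorticoid response genes 5 were lower adjusted over the list alone and 0 over all genes, with Nfkbia, an inhibitor of NF-kappaB, at −0.69 (SE 0.12, edgeR adjusted p = 0.133) and Ddit4 at −0.52 (SE 0.10, edgeR adjusted p = 0.170). That list's camera call (adjusted p = 5.94e-05, median −0.14) was lost at adjusted p = 0.380 with an estimated correlation.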

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

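The tests of cord steroid synthesis and of adrenal and lung tissue, and the alternative without male 8-week libraries 2 and 3, were chosen only after the transcripts had been seen.

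Star and Cyp11a1 stood out because their age changes differed between the sexes in the interaction test, by 2.01 and 4.49 on the log2 scale. Both belong to the adrenal cortex list, adrenal transcripts lie in both male 4-week libraries, and lung transcripts in male 8-week libraries 2 and 3. Steroid synthesis by the male 4-week cord itself is argued against by Dbh, an enzyme of adrenal medulla, whose ratio in these libraries over the other 8 had a lower 95% bound of 9.43, and by Pnmt, at least 71.1-fold higher against a floor of 3 counts over the other 8. A candidate explanation is RNA of adrenal tissue, whose genes would keep like proportions. Over 10 adrenal genes chosen for being higher there, the counts of male 4-week libraries 1 and 2 did (chi-square over degrees of freedom 0.820). Cyp11a1 was among those 10. Star, with a ratio of 4.25 over the other 8 libraries, fell below the limit for that choice and was not in that test. RNA of lung tissue is likewise a candidate, since over 12 lung genes the log2 ratio of male 8-week library 2 to library 3 had an SD of 0.292. Tissue of 1 or of several animals would give like proportions, so the number of sources stays open, how such RNA reached the libraries was not tested, and a difference of sex or age in the animals stays open as untested.

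In the interaction test Star was called in every alternative but the one without male 8-week libraries 2 and 3 (adjusted p = 0.0728, over the alternatives 1.01e-08 to 0.0728). Cyp11a1 lost its call in limma-voom (adjusted p = 0.0943), without male 8-week libraries 2 and 3 (0.224), and by edgeR without female 4-week library 1 (0.0652) or 2 (0.179), male 8-week library 1 (0.0746), or female 8-week library 1 (0.0677), 2 (0.109) or 3 (0.0942), over a range of 4.18e-05 to 0.224.

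Camera called 9 lists in the interaction, while 0 of their members passed by edgeR over all genes. Positive medians, a higher change in females, were found for neutrophil and marrow genes (0.68, adjusted p = 8.34e-04), erythroid genes (0.59, adjusted p = 0.00285), Y-linked genes (0.40, adjusted p = 0.0370), cell division genes (0.31, adjusted p = 0.00542) and myelin genes (0.04, adjusted p = 0.0470). Negative medians were found for immediate early genes (−0.30, adjusted p = 0.0470), glucocorticoid response genes (−0.24, adjusted p = 0.00285), circadian clock genes (−0.19, adjusted p = 0.0216) and inhibitory neuron genes (−0.07, adjusted p = 0.0470). All these calls were lost, at adjusted p = 0.880 with an estimated correlation and 0.870 by fry. Of the Y-linked genes, Ddx3y (2.75, edgeR adjusted p = 0.970) and Uty (−2.14, 0.981) took most of their values from single counts in female libraries, and Eif2s3y and Kdm5d, with 0 counts there, took theirs from the male libraries.

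Anln, a septin-binding protein of myelin, was lower at 8 weeks in every male library and higher in every female library than in the 4-week libraries of the same sex. Its interaction value was 0.48 (SE 0.11), which did not pass over all genes (edgeR adjusted p = 0.970). Anln was found by looking through 216 named genes, of which 2 went opposite ways in every library. With 2 libraries against 3, full separation arises by chance in 20% of genes in each sex. Opposite separation in 2 of 216 genes is therefore no more than chance alone would give.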

How the results depend on the processing

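The 3 alternatives that leave out male 8-week libraries 2 and 3, leave out both male 4-week libraries or add the muscle score were chosen after seeing the data, and the others before. Of 2078 values of the 101 named gene results under alternatives, 1800 kept their direction and their side of the threshold, 274 kept their direction and lost the call, and 4 reversed. The values for lists were counted together with the numbers of lists called, which have no direction and no side of the threshold. Of these, 109 list values lost the call, 4 reversed, and 5 numbers of lists moved. The remaining 522 were list values that kept both or numbers of lists that stayed close. DESeq2 gave no adjusted p for Ddx3y, Eif2s3y, Kdm5d, Cyp21a1 and Hsd3b1 at 4 weeks, and these are not counted. No call changed sign when a library was left out. With the muscle score as a covariate, Myh2 stood at 0.22, Ucp1 at 0.27, Gria1 at −0.10 and Pvalb at 0.82, and the directions of the inhibitory neuron (adjusted p = 0.366), excitatory neuron (0.898), fast-firing axon channel (0.647) and skeletal muscle lists (0.647) reversed. That score carries age (Pearson r = −0.912) and raised the median SE 2.42-fold, so fewer calls for age follow from its construction. Depth limits genes near 1 CPM most.

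Leaving out each library in turn gave 719 to 1473 genes for age over both sexes, 10 to 28 for sex over both ages, 188 to 1199 for age in males, 62 to 394 for age in females, 10 to 116 for sex at 4 weeks, 5 to 9 for sex at 8 weeks and 1 to 2 for the interaction, and 10 to 15 lists for sex over both ages. The male count was 1199 without male 4-week library 2, 247 without male 4-week library 1, 239, 188 and 258 without male 8-week libraries 1, 2 and 3, and 301 without female 8-week library 1. The female count was 392 and 394 without male 4-week libraries 1 and 2, 94 and 68 without female 4-week libraries 1 and 2, and 62, 141 and 66 without female 8-week libraries 1, 2 and 3. At 4 weeks the sex count was 116 without male 4-week library 2, over both ages it was 28 without that library and 24 without male 8-week library 2, and the number of lists was 10 without male 8-week library 2. The interaction count was 1 without either female 4-week library, male 8-week library 1 or any female 8-week library. Where an arm kept 1 library, that library is assumed to vary like the other groups. The cause was not tested.

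Without male 8-week libraries 2 and 3 the counts were 474 for age over both sexes, 15 for age in males, 118 for age in females and 0 for the interaction. Without both male 4-week libraries they were 393 for age over both sexes, which then is age in females, and 9 for sex over both ages, which then is sex at 8 weeks, and no value for age in males, or of Y-linked genes with age, can be had. Of the myelin and sterol synthesis genes 11 and 13 were lower without the former libraries, and 12 and 12 without the latter. Adding the muscle score gave counts of 41 for age over both sexes, 41 for age in males, 15 for age in females, 24 for sex over both ages, 18 for sex at 4 weeks, 13 for sex at 8 weeks, and 7 lists for age. Without a filter for low counts they were 60 for sex over both ages, 340 for age in females, 17 for sex at 4 weeks and 34 for sex at 8 weeks, and the strict filter left 7 for sex at 4 weeks. DESeq2 called 35 for sex over both ages, 31 for sex at 4 weeks and 26 for sex at 8 weeks, and limma-voom called 1 for the interaction. A fit of only the groups compared called 175 for age in males, 398 for age in females and 19 for sex at 8 weeks, and the mean of the 4-group contrasts called 9 for sex over both ages. With an estimated correlation 2 lists were called for age and 2 for sex, and fry called 2 for sex. Other scalings moved no count by over 1.5 times. The causes were not tested.

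Whether the replicate numbers pair the samples stays open. Of 13 pairs with the same number, 5 had a correlation of their deviations over 0.1 (from −0.213 to 0.236). Of 10 libraries 2 correlated best with their own number. In a group of 2 libraries the deviations mirror each other, so these correlations are not independent and cannot exclude pairing. With the replicate number as a block, 808 genes were called for age over both sexes, 38 for sex over both ages and 23 for sex at 8 weeks.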

Other observations

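The genes of the following paragraph, the tests of a lower oligodendrocyte share and of dividing marrow cells, and the muscle score covariate were chosen only after the results had been seen.

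Of single genes outside the lists, picked for their values and not tested as a group, 7 of those named here were lower and 2 higher at 8 weeks over both sexes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Elovl1, which lengthens fatty acids, fell by 0.73 (SE 0.06, adjusted p = 4.58e-06), Cers2, a ceramide synthase, fell by 0.53 (SE 0.05, adjusted p = 2.13e-05), and Gal3st1, which makes the myelin lipid sulfatide, fell by 0.67 (SE 0.07, adjusted p = 2.96e-05). Aacs, which supplies acetoacetyl-CoA for sterol and fatty acid synthesis, fell by 0.75 (SE 0.06, adjusted p = 3.50e-06), and Elovl6 fell by 0.57 (SE 0.06, adjusted p = 8.75e-05). Gsn, an actin-severing protein, fell by 1.08 (SE 0.06, adjusted p = 1.96e-07), and Tspan2, a tetraspanin of oligodendrocytes, fell by 0.81 (SE 0.06, adjusted p = 1.73e-06). Qdpr, which recycles a cofactor of aromatic amino acid hydroxylases, rose by 0.57 (SE 0.08, adjusted p = 7.17e-04), and Pkd2l1, a channel of cells that contact the cerebrospinal fluid, rose by 0.86 (SE 0.11, adjusted p = 2.08e-04). The changes of these 9 genes had the same sign in males and in females, and they were not followed under the alternatives.

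At 8 weeks 13 of 22 myelin, 17 of 19 sterol synthesis and 9 of 12 newly forming oligodendrocyte genes were lower and Bcas1 was higher, and the camera call of the myelin list was lost at adjusted p = 0.124 with an estimated correlation. After a trend of log2 fold change on GC content and transcript length was subtracted, the 39 members called lower had a median of −0.53, against −0.56 before, which argues against that bias, and with the Schwann cell score as a covariate 13 of 22 myelin genes were called lower, which argues against nerve root tissue. A lower share of mature oligodendrocytes as the only change predicts 1 equal fall of all members if only those cells make them. The SD of the members was 5.22 times their median SE, which argues against 1 equal fall. Whether other cells make some members was not tested, so a lower share stays open. With the muscle score as a covariate 3 of 22 myelin genes were lower, at a median of −0.13 (median SE 0.14, from −0.39 and 0.06), and 0 of 19 sterol synthesis genes, at −0.32 (median SE 0.16, from −0.41 and 0.07). Since that score carries age, the fit cannot tell age from attached tissue, which stays open as a source of part of the change. Age itself stays open as an untested explanation.

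Higher at 4 weeks were 12 of 12 muscle, 6 of 11 cartilage and bone, 8 of 8 fat cell, 12 of 12 marrow, 6 of 9 erythroid and 13 of 20 collagen genes, and the camera calls, which the fat list did not have, were lost at adjusted p values between 0.103 and 0.205 with an estimated correlation. Varying amounts of attached tissue fit the spread within groups: the median SD of called members over that of 10000 random lists matched on expression was 5.01 for muscle, bone and fat (26 genes), 2.64 for marrow and blood (18 genes) and 2.21 for connective tissue (13 genes), each above 100% of those lists. Without male 4-week library 1 these were 4.51, 2.53 and 2.04. Tissue left on the cord in unequal amounts is therefore a candidate source, and age itself stays open as untested. Of the markers, Alpl is also expressed in cord. Sparc, the most abundant collagen matrix gene, lay between 1734 and 2694 CPM, in a list with a summed level of 2449 to 4461 CPM. The source of Sparc was not tested, so that summed level cannot be read as attached tissue alone.

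For cell division genes, a hypothesis is that dividing marrow cells carry part of the change. Over the 10 libraries the deviations of the cell division score from the age means followed those of the marrow score with a Pearson r of 0.867 (exact permutation p = 0.00972) and a Spearman rho of 0.758 (exact permutation p = 0.0325), the only relation tested in this family. Without the 2 libraries whose marrow score deviations lay farthest from the median deviation, male 4-week library 1 and female 4-week library 1, r was 0.769 (exact permutation p = 0.0431). Age itself stays open as untested.

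Other splits of the libraries were counted for the numbers of genes called. For age over both sexes 100 of 210 possible splits were run. The real split gave 1028 genes and the highest of the others 556, and 1 of the 100, the real one, reached that number. That share is under 0.05 for a chance split of these libraries. They may not come from separate animals, so chance between animals cannot be excluded. For the count of genes by sex over both ages chance cannot be excluded, since 6 of the 100 splits run, of 126 possible, reached the real 14. The highest of the others gave 1955. That split set male 4-week library 1, female 4-week library 1, male 8-week libraries 1 and 2 and female 8-week library 2 against the rest. Its size points to a structure of the samples other than sex. Within each age the libraries named had the higher skeletal muscle scores, 3.202 and 1.595 against 1.146 and 1.536 at 4 weeks. At 8 weeks these were −0.857, −0.655 and −0.606 against −1.656, −1.383 and −2.323. Their ribosomal protein scores, 0.017 to 0.33, lay above those of the rest, −0.241 to −0.06. Both lists were picked after the split was seen, and the cause was not tested. For sex at 8 weeks the 10 splits are too few for a share under 0.05, with 7 genes for the real split, the 1 that reached this number, and 4 for the highest other.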
